A study of Homo sapiens with 8 samples.

How the data were processed

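Polyadenylated RNA from MCF10A cells was sequenced in 8 libraries, 2 for each of 4 siRNA treatments. Per the labels' protocols, libraries were made with the TruSeq RNA version 2 kit, which does not keep strand, were barcoded and shared a lane, and the replicates were independent batches of cells. Per the submitters' processing notes, TopHat and the hg19 genome build were used, without versions. The read counter, the annotation, the scaling and the reason for the floor are not given in the sources used here. The deposited values were taken as log2 expression levels. Converted to the linear scale with base 2, low values lay near an even spacing, more closely in some libraries than in others. No comparison with other bases is reported here. Every value below 5 (32 on the linear scale) had been set to 5 before deposit, which understates changes of low genes. The per-library columns held the same values as the series table for 8 of 8 libraries. The summed linear signal above the floor was 23.7 to 24.9 M per library.

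The depth was not given. From the spacing of linear values between 32 and 80, taken as the worth of a read, it was estimated at 12.1 and 25.8 M reads for siControl, 37.1 and 22.4 for siLATS, 29.5 and 25.6 for sip53, and 11.3 and 30.8 for siLATS_p53, so that the floor stood for 14.6 to 50 reads. These are estimates, and no counts could be recovered, so no count-based test was run.

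Differences were tested with limma 3.58.1 in R 4.3.3 with a mean-variance trend, in 1 fit over the 4 groups (4 residual degrees of freedom), on the deposited log2 values. No pseudocount was added, because the values were already logged and floored, although the design fixed before the data were examined named a pseudocount of 1; adding it changed the calls of a comparison by 2 at most. Entries above the floor in at least 2 libraries were tested (12315 of 29991, with 17422 at the floor in all libraries), and p-values were adjusted by the Benjamini-Hochberg method over them with a threshold of 0.05. Entries repeating a symbol (147 of those tested) and members of families with near-identical copies were not named. The comparisons were each knockdown against control, each knockdown on top of the other, and their interaction.

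Same-numbered libraries share a batch of cells per the labels. Their deviations from the group means correlated between 0.565 and 0.726 over the 6 pairs of groups, and a principal component with 21.5% of the variance separated the batches. Another, with 30.9%, was higher in batch 2 than in batch 1 within each of the 4 groups. The fit with the batch as a block is therefore printed where it changes the call of a printed gene or of a list. It is also printed where it moves the number of genes called in a comparison by over 1.5 times. The gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The rule took the knocked-down genes, the 10 largest rises and falls (5 for the last 3 comparisons) among called genes above the median expression level with treated and control libraries apart, up to 4 members of a list with the smallest p, and the readouts CTGF, CYR61, ANKRD1, CDKN1A, MDM2 and CDH1. The results of some genes taken by this rule are not reported here.

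The 21 lists tested held YAP/TAZ targets, p53-activated targets, S phase, G2/M, mesenchymal, epithelial junction, adhesion and migration, Hippo pathway, basal, luminal, squamous, fibroblast, blood and endothelial, interferon-stimulated, NF-kB, cholesterol synthesis, ATF4 and unfolded protein response, immediate early, TGF-beta, hypoxia and histone genes. Each was tested with limma's camera with a preset correlation of 0.01, adjusted over the lists in a comparison. The test was repeated with an estimated correlation, which kept 2 of 40 calls (p53 targets in both p53 contrasts). That correlation was estimated only in the fit without the batch block, so batch differences shared by members of a list enter it. List tests with the block used the preset correlation alone. A list of mitochondrially encoded genes had no entry under its symbols and was not tested, and SFN was not analysed here. In 29 of 126 list tests, none of them called, the sign of the median or mean differed from that of camera, which compares a list with the other genes.

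The alternatives were rescaling by medians of ratios, other filters, pseudocounts, the batch block, only the groups compared, each library left out in turn, other list tests and, added after seeing the data, the block with rescaling, leaving out the 2 shallowest libraries, rescaling for slopes and overlaps, and the pseudocount of 1 as an alternative. Without 1 library a group keeps a lone sample, which is assumed to vary like the other groups. The fits with libraries left out had no batch block. Leaving out a library of a compared group therefore also lets batch differences into the comparison. Shared controls were simulated in 100 draws. The procedure was tested on simulated data for LATS1/2 knockdown against control with 12315 genes, of which 200 changed. The changed genes were drawn from those above the median expression level, and the noise was drawn independently for each gene. The rates below therefore do not cover low genes or genes that vary together. Of 50 genes per size, limma called 28% at a log2 change of 0.5, 78% at 1, 96% at 1.5 and 98% at 2, with 0 false calls among 150. With the batch as a block these were 64%, 96%, 100% and 100%, with 5 false calls among 185. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.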

Results

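Messenger RNA was sequenced from MCF10A cells, an immortalised line of non-tumorigenic human breast epithelium with basal features. The cells had been transfected with a control siRNA, with siRNA against the Hippo pathway kinases LATS1 and LATS2, with siRNA against p53, or with all of these siRNAs together. These groups are called siControl, siLATS, sip53 and siLATS_p53 here. Each of the 4 groups had 2 libraries, and per the labels the libraries numbered 1 and 2 came from independent batches of cells, so that 8 libraries entered each fit. The deposited values were taken as normalised log2 expression levels with a floor of 5. Of the 29991 entries, 12315 lay above that floor in at least 2 libraries and were tested. Between 11756 and 12064 entries were above the floor in a library. Depth was not given, and the spacing of low values put it between 11.3 and 37.1 M reads per library. All fold changes below are differences of log2 values with their standard error (SE) from limma, and adjusted p-values are Benjamini-Hochberg values over the genes tested.

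The siRNAs against LATS1 and LATS2 lowered both genes in every library that received them. LATS1 was 9.59 ± 0.07 (SD, n = 2) in siControl, 8.02 ± 0.12 in siLATS, 9.90 ± 0.05 in sip53 and 7.93 ± 0.05 in siLATS_p53, on the log2 scale. LATS2 was 10.07 ± 0.21 (SD, n = 2) in siControl, 8.67 ± 0.06 in siLATS, 9.87 ± 0.18 in sip53 and 8.78 ± 0.04 in siLATS_p53. Against control, LATS1 was 2.98-fold lower and LATS2 2.63-fold lower in siLATS.

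**Figure D1:**
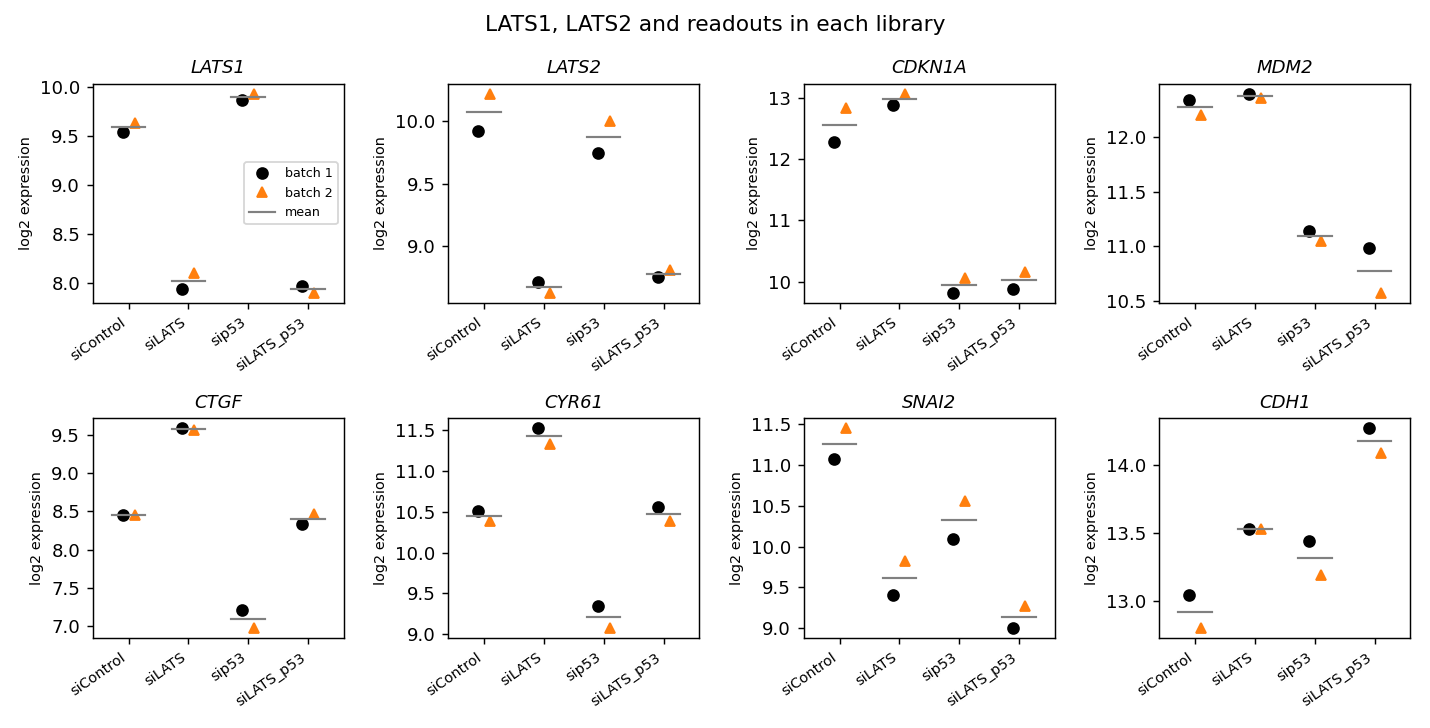
Log2 expression (vertical axes, each with its own range) of LATS1, LATS2 and 6 readout genes in the 8 libraries, by group (horizontal axes). Points are single libraries, with batch 1 as circles and batch 2 as triangles, and grey lines are the means of 2 libraries; CTGF was 8.45 in siControl, 9.58 in siLATS, 7.09 in sip53 and 8.40 in siLATS_p53.

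The first comparison asked what LATS1/2 knockdown alone changed. Among called genes above the median expression level, the carboxypeptidase gene CPA4 had the largest rise (3.20 ± 0.19), followed by the simple epithelial keratin gene KRT8 (1.98 ± 0.38), CCDC80 (1.95 ± 0.26) and the tight junction gene CGN (1.93 ± 0.09). Targets of YAP and TAZ, the transcriptional coactivators that LATS kinases restrain, were among the genes that rose. SNAI2, which encodes the transcription factor SLUG, fell by 1.65 ± 0.21, and 10 of 40 S phase genes and 16 of 40 G2/M genes fell. CDKN1A, the p53 target that encodes p21, differed by 0.42 ± 0.19 (adjusted p = 0.224). With the batch as a block CDKN1A passed (adjusted p = 0.0022).

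Of 31 YAP/TAZ target genes tested, 16 rose, 0 fell and 15 did not pass; adjusted over the list alone, 20 rose and 2 fell. The matrix glycoprotein THBS1 rose by 1.84 ± 0.15, the coagulation initiator F3 by 1.73 ± 0.13, the angiomotin-like gene AMOTL2 by 1.31 ± 0.10 and CTGF by 1.12 ± 0.13. CYR61, another usual readout, rose by 0.97 ± 0.13. The list moved up relative to the other genes (camera, adjusted p = 5.27e-14), with adjusted p = 0.132 with an estimated correlation. ANKRD1 lay at the floor in siControl and is given no fold.

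Some epithelial genes rose and some cell division genes fell in the same comparison. Of 29 epithelial junction genes 10 rose and 1 fell (14 and 1 adjusted over the list alone), among them CGN, the claudin gene CLDN1 (0.92 ± 0.09) and the protease gene ST14 (0.75 ± 0.08), while the desmosomal cadherin gene DSC3 fell by 0.67 ± 0.09. The camera adjusted p was 6.60e-08, with adjusted p = 0.155 with an estimated correlation. CDH1, which encodes E-cadherin, rose by 0.61 ± 0.12. Of 12 luminal markers 3 rose (5 up and 1 down adjusted over the list alone), namely CD24 (1.62 ± 0.21), KRT8 and KRT18 (0.69 ± 0.16), with a camera adjusted p of 0.00093 and adjusted p = 0.50 with an estimated correlation. Of 40 S phase genes 10 fell (22 adjusted over the list alone), such as the replication genes GINS2 (-0.80 ± 0.12) and MCM6 (-0.53 ± 0.08), and of 40 G2/M genes 16 fell (33 adjusted over the list alone), such as the centromere histone gene CENPA (-1.01 ± 0.13). The camera adjusted p-values were 1.5e-07 and 2.5e-12, and with an estimated correlation adjusted p = 0.155 and adjusted p = 0.49.

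Other large changes after LATS1/2 knockdown included rises of ADM (1.61 ± 0.12), GPRC5A (1.57 ± 0.09) and NCEH1 (1.55 ± 0.12). PID1 fell by 1.79 ± 0.22, IARS2 by 1.66 ± 0.14, FLRT3 by 1.56 ± 0.15, DNER by 1.47 ± 0.19, MTSS1 by 1.44 ± 0.26, METTL9 by 1.41 ± 0.23, SERPINB5 by 1.40 ± 0.18, B3GALNT2 by 1.30 ± 0.11 and OSTM1 by 1.28 ± 0.22. Mesenchymal genes split, with 3 of 23 up, including FBN1 (1.72 ± 0.14) and TAGLN (1.48 ± 0.12), and 4 down, including VIM (-0.80 ± 0.09). Adhesion and migration genes split likewise, with 4 of 41 up, such as the myosin light chain gene MYL9 (1.41 ± 0.18), and 4 down, such as the integrin gene ITGA2 (-0.89 ± 0.13). Adjusted over each list alone, 3 and 4 mesenchymal genes and 5 and 6 adhesion and migration genes rose and fell. Of 44 p53-activated targets 4 rose and 2 fell (4 and 5 adjusted over the list alone), with PLK2 up by 1.52 ± 0.09 and GADD45A by 0.87 ± 0.14, PERP down by 0.67 ± 0.11, and a camera adjusted p of 0.317. None of 30 interferon-stimulated genes passed singly, although the list moved up (camera, adjusted p = 6.6e-08; adjusted p = 0.66 with an estimated correlation). That call was lost without siLATS replicate 1 (adjusted p = 0.0783), and with the batch as a block 25 members rose.

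For the remaining lists, up and down calls were 3 and 3 of 28 Hippo pathway components, 1 and 1 of 19 basal markers, 2 and 1 of 22 squamous markers, 1 and 0 of 5 fibroblast markers, and 0 and 0 of 3 blood and endothelial markers. They were 1 and 3 of 24 NF-kB genes, 1 and 0 of 24 cholesterol synthesis genes, 1 and 2 of 28 ATF4 and unfolded protein response genes, 1 and 4 of 24 immediate early genes, 1 and 3 of 21 TGF-beta response genes and 2 and 1 of 27 hypoxia genes. Adjusted over each list alone the counts changed to 4 and 6 for Hippo components, 2 and 2 for squamous markers, 1 and 4 for NF-kB genes, 4 and 8 for immediate early genes and 2 and 2 for hypoxia genes. None of these lists passed camera without the block, and with it basal markers (adjusted p = 0.0030) and NF-kB genes (adjusted p = 0.043) moved down. Without the block and with an estimated correlation, both of these had a camera adjusted p of 0.80. Of 4 histone genes 1 rose (camera, adjusted p = 0.0068; adjusted p = 0.41 with an estimated correlation), a call lost without siControl replicate 2 (adjusted p = 0.0527). In the 2 siLATS libraries the 10 highest entries, several of them mitochondrial, took 13.9% and 15.5% of the summed linear signal, against 11.6% and 13% in siControl.

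In all, 948 genes passed for LATS1/2 knockdown, 346 higher (36.5%) and 602 lower, and 203 of them changed at least 2-fold. With the batch as a block 3937 passed, and after rescaling by medians of ratios 55.4% of the calls were higher. The count was 189 without siControl replicate 1, 214 without siControl replicate 2, 43 without siLATS replicate 1, 122 without siLATS replicate 2, 429 without sip53 replicate 1 and 421 without sip53 replicate 2. Of the 78 called genes named by rule, 17 passed whichever library was left out, and none changed direction.

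Knockdown of p53 alone lowered known p53 targets and raised some cell division genes. Among called genes above the median expression level, CDKN1A had the largest fall (-2.62 ± 0.19), followed by the phosphatase gene INPP5D (-2.58 ± 0.18), the secreted lipase inhibitor gene ANGPTL4 (-2.08 ± 0.17), PLCH2 (-1.86 ± 0.28) and the fibronectin gene FN1 (-1.79 ± 0.23). Of 44 p53-activated targets 19 fell and 0 rose (31 fell adjusted over the list alone), including TP53INP1 (-2.39 ± 0.15), ABCA12 (-1.10 ± 0.09), PLK2 (-1.10 ± 0.09) and MDM2, the ubiquitin ligase gene that restrains p53 (-1.18 ± 0.13). This list passed camera with the preset correlation (adjusted p = 5.6e-28) and with an estimated correlation (adjusted p = 0.038).

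Of 40 S phase genes 13 rose and 0 fell after p53 knockdown (30 rose adjusted over the list alone), with E2F2 up by 1.04 ± 0.17, the ribonucleotide reductase gene RRM2 by 0.71 ± 0.10 and the cyclin gene CCNE2 by 0.70 ± 0.11. Of 40 G2/M genes 12 rose and 0 fell (32 rose adjusted over the list alone), with the kinesin gene KIF20A up by 0.66 ± 0.10. The camera adjusted p-values were 1.5e-12 and 8.3e-15, and with an estimated correlation adjusted p = 0.088 and adjusted p = 0.28. YAP/TAZ targets fell in 4 of 31 cases (1 up and 11 down adjusted over the list alone), among them CTGF (-1.36 ± 0.13), CYR61 (-1.24 ± 0.13) and EDN1 (-0.61 ± 0.13), with a camera adjusted p of 5.6e-07 and adjusted p = 0.128 with an estimated correlation. The gene of the coactivator itself, YAP1, fell by 0.64 ± 0.11.

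Some mesenchymal, adhesion and immediate early genes also fell after p53 knockdown. Of 23 mesenchymal genes 4 fell (6 adjusted over the list alone), namely FN1, TAGLN (-1.23 ± 0.12), ACTA2 (-1.12 ± 0.21) and VIM (-0.50 ± 0.09), with a camera adjusted p of 0.00051. Of 41 adhesion and migration genes 4 fell and 1 rose (8 and 1 adjusted over the list alone), with MYL9 down by 1.53 ± 0.18 and the laminin gene LAMB3 by 0.93 ± 0.18, and a camera adjusted p of 6.6e-05. Both lists had adjusted p = 0.13 with an estimated correlation. Of 24 immediate early genes 5 fell (9 adjusted over the list alone), with EGR1 down by 1.19 ± 0.11, a camera adjusted p of 2.7e-07 and adjusted p = 0.22 with an estimated correlation. CDH1 differed by 0.39 ± 0.12 (adjusted p = 0.132; 0.0016 with the batch as a block).

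Other rises after p53 knockdown were those of the carbonic anhydrase gene CA2 (1.40 ± 0.13), PEG10 (1.17 ± 0.13), CGN (1.02 ± 0.09), ATP6V0E2 (0.81 ± 0.11), HPSE (0.75 ± 0.10), H1F0 (0.75 ± 0.09), SH3RF2 (0.73 ± 0.09), GJB2 (0.72 ± 0.15) and LYN (0.72 ± 0.10). FADS3 fell by 1.67 ± 0.16, RRM2B by 1.52 ± 0.16, LPGAT1 by 1.42 ± 0.11 and ELOVL7 by 1.32 ± 0.13. With the batch as a block the camera calls of interferon-stimulated genes (up, adjusted p = 0.017), NF-kB genes (down, 0.019), Hippo components (down, 0.033) and histone genes (down, 0.034) were added. Without the block and with an estimated correlation, these lists had camera adjusted p-values of 0.465 or above. In all, 475 genes passed, 217 higher (45.7%) and 258 lower, and 26.3% of the calls were higher after rescaling. With the block 3199 passed, 1965 higher (61.4%) and 1234 lower, and with the block and rescaling 1332 were higher (44.8%) and 1643 lower, so that the balance depended on the scaling.

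The p53 knockdown count depended on every library, although the siLATS and siLATS_p53 libraries enter it only through the estimate of spread. It was 34 without siControl replicate 1, 46 without siControl replicate 2, 39 without siLATS replicate 1, 39 without siLATS replicate 2, 19 without sip53 replicate 1, 18 without sip53 replicate 2, 165 without siLATS_p53 replicate 1 and 164 without siLATS_p53 replicate 2. Of the 61 called genes named by rule, 6 passed whichever library was left out.

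Combined knockdown was compared with control to see the joint outcome. The p53 targets CDKN1A (-2.54 ± 0.19) and MDM2 (-1.49 ± 0.13) fell, CPA4 (2.81 ± 0.19), CGN (2.51 ± 0.09), KRT8 (2.26 ± 0.38) and CDH1 (1.26 ± 0.12) rose, and SNAI2 fell by 2.13 ± 0.21. ELF3, an epithelial transcription factor gene, rose by 2.48 ± 0.29 and ERBB3 by 1.91 ± 0.21. CTGF (-0.05 ± 0.13, adjusted p = 0.819) and CYR61 (0.02 ± 0.13, adjusted p = 0.935) did not pass, after changing in opposite directions under the single knockdowns.

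Of 44 p53-activated targets 26 fell and 1 rose (29 and 1 adjusted over the list alone; camera, adjusted p = 3.7e-20), with adjusted p = 0.070 with an estimated correlation. Of 31 YAP/TAZ targets 14 rose and 2 fell (16 and 2 adjusted over the list alone), with THBS1 up by 1.26 ± 0.15, F3 by 1.17 ± 0.13, AMOTL2 by 1.05 ± 0.10 and WWC1 by 0.87 ± 0.09, a camera adjusted p of 0.0050 and adjusted p = 0.45 with an estimated correlation. Of 29 epithelial junction genes 15 rose and 2 fell (17 and 2 adjusted over the list alone), with GRHL3 up by 1.44 ± 0.12, ST14 by 1.32 ± 0.08 and CLDN1 by 1.12 ± 0.09, a camera adjusted p of 4.0e-05 and adjusted p = 0.29 with an estimated correlation. Of 40 S phase genes 12 rose and 0 fell (19 rose adjusted over the list alone; camera, adjusted p = 5.9e-06; adjusted p = 0.29 with an estimated correlation), and of 40 G2/M genes 15 rose and 1 fell (24 and 1 adjusted over the list alone; 5.0e-05; adjusted p = 0.67 with an estimated correlation).

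Of 24 immediate early genes 8 fell and 3 rose (11 and 4 adjusted over the list alone) after combined knockdown, with EGR1 down by 2.32 ± 0.11 and DUSP6 by 1.36 ± 0.09, a camera adjusted p of 0.00015 and adjusted p = 0.45 with an estimated correlation. Of 30 interferon-stimulated genes 5 rose (7 adjusted over the list alone), such as the RNA sensor gene IFIH1 (1.26 ± 0.27), and 26 with the batch as a block, with a camera adjusted p of 0.00013 and adjusted p = 0.67 with an estimated correlation. Luminal markers rose in 5 of 12 cases and fell in 1, AREG (-1.41 ± 0.21), with a camera adjusted p of 0.066 and of 0.0033 with the block. Basal markers, of which S100A2 (-1.53 ± 0.23), TP63 (-0.92 ± 0.17) and COL17A1 (-0.99 ± 0.21) fell and LAMA5 (0.70 ± 0.11) rose, had a camera adjusted p of 0.10, and of 0.0039 with the block. Mesenchymal genes had 0.063, and 0.019 with the block. With an estimated correlation and no block, the camera adjusted p was 0.67 for luminal markers, 0.67 for basal markers and 0.45 for mesenchymal genes. The interleukin gene IL6 was at the floor in both siControl libraries and passed, so that its value of 2.19 on the log2 scale is a lower bound.

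Other large changes after combined knockdown were rises of CA2 (1.90 ± 0.13), SERPINB2 (1.75 ± 0.09), COL12A1 (1.74 ± 0.18), NCEH1 (1.72 ± 0.12) and PODXL (1.67 ± 0.25). INPP5D fell by 3.07 ± 0.18, PLCH2 by 2.08 ± 0.28, LPGAT1 by 2.01 ± 0.11, ANGPTL4 by 1.99 ± 0.17, COPS8 by 1.90 ± 0.15, FLRT3 by 1.87 ± 0.15, CA12 by 1.82 ± 0.08 and RRM2B by 1.78 ± 0.16. In all, 1792 genes passed, 1117 higher (62.3%) and 675 lower, against 4832 with the block, and 47.5% of the calls were higher after rescaling. The count was 637 without siControl replicate 1, 1068 without siControl replicate 2, 1164 without siLATS replicate 1, 1166 without siLATS replicate 2, 553 without siLATS_p53 replicate 1 and 709 without siLATS_p53 replicate 2. Of the 95 called genes named by rule, 55 passed whichever library was left out.

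**Figure D2:**
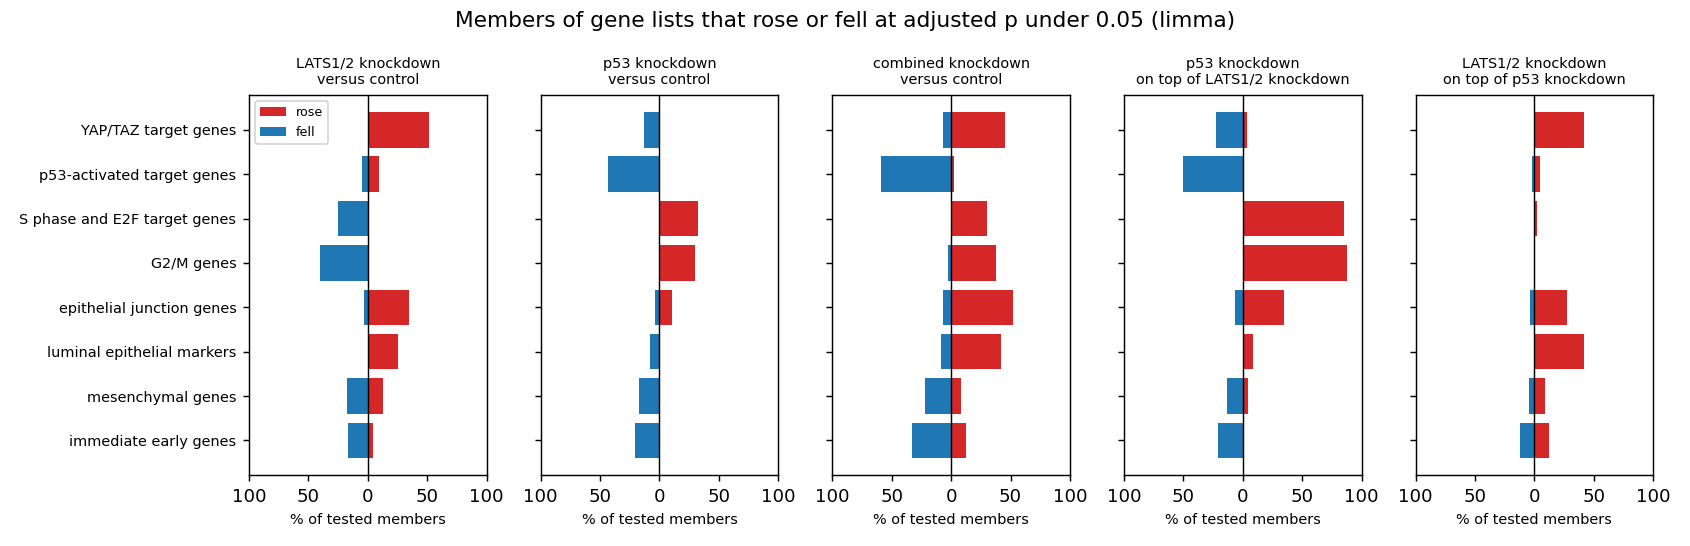
Percent of the tested members of 8 gene lists (vertical axis) that rose (red, to the right) or fell (blue, to the left) at an adjusted p under 0.05 from limma without the batch block, in 5 comparisons (panels, horizontal axes in percent). Of S phase and G2/M genes, 10 and 16 of 40 fell with LATS1/2 knockdown, and 34 and 35 of 40 rose with p53 knockdown on top of it.

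Adding p53 knockdown to LATS1/2 knockdown showed which changes depended on p53 siRNA in cells with less LATS1/2. Cell division genes rose almost throughout, with 34 of 40 S phase genes and 35 of 40 G2/M genes up and 0 down in either list (36 and 39 up adjusted over each list alone). RRM2 rose by 1.05 ± 0.10, MCM2 by 0.81 ± 0.08, KIF20A by 0.93 ± 0.10 and the mitotic transcription factor gene FOXM1 by 0.90 ± 0.08. ELF3 rose by 2.04 ± 0.29, CA2 by 1.64 ± 0.13, NMU by 1.40 ± 0.26, AQP3 by 1.38 ± 0.35 and PPL by 1.32 ± 0.27. CDKN1A fell by 2.95 ± 0.19, INPP5D by 2.86 ± 0.18, PLCH2 by 2.06 ± 0.28, FADS3 by 1.74 ± 0.16 and MDM2 by 1.60 ± 0.13.

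The camera adjusted p-values of the S phase and G2/M lists were 3.7e-16 and 3.1e-17 in this comparison, with adjusted p = 0.055 and adjusted p = 0.32 with an estimated correlation. Of 44 p53-activated targets 22 fell and 0 rose (28 fell adjusted over the list alone), and this list passed with the preset correlation (adjusted p = 2.1e-29) and with an estimated correlation (adjusted p = 0.034). YAP/TAZ targets fell in 7 of 31 cases and rose in 1 (8 and 1 adjusted over the list alone), with CTGF down by 1.18 ± 0.13, CYR61 by 0.95 ± 0.13 and CRIM1 by 0.91 ± 0.16, and BIRC5, which is also a mitotic gene, up by 1.02 ± 0.13. The camera adjusted p was 2.2e-06, with adjusted p = 0.17 with an estimated correlation. Of 23 mesenchymal genes 3 fell and 1 rose (4 and 1 adjusted over the list alone; camera, adjusted p = 0.0018; adjusted p = 0.17 with an estimated correlation), and of 24 immediate early genes 5 fell (5 adjusted over the list alone; 0.00063; adjusted p = 0.46 with an estimated correlation). Of 4 histone genes 0 passed singly (camera down, adjusted p = 0.019; adjusted p = 0.36 with an estimated correlation), and the list did not pass after rescaling (adjusted p = 0.0659), without siLATS replicate 1 (0.0832) or without siLATS_p53 replicate 2 (0.113).

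In all, 1791 genes passed for p53 knockdown on top of LATS1/2 knockdown, 1395 higher (77.9%) and 396 lower, against 5361 with the block. The median of all genes was shifted by 0.15 on the log2 scale in this comparison, and after rescaling 45.8% of 1205 calls were higher. The count was 12 without siLATS replicate 1, 143 without siLATS replicate 2, 67 without siLATS_p53 replicate 1, 1019 without siLATS_p53 replicate 2, 1019 without sip53 replicate 1 and 1007 without sip53 replicate 2. Of the 61 called genes named by rule, 7 passed whichever library was left out.

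LATS1/2 knockdown was also measured in cells that had received p53 siRNA. CPA4 (3.24 ± 0.19), CCDC80 (2.27 ± 0.26), KRT8 (2.20 ± 0.38), SERPINB2 (1.99 ± 0.09) and CD24 (1.93 ± 0.21) rose most among called genes above the median expression level, and EMB (-1.60 ± 0.14), IARS2 (-1.59 ± 0.14), FLRT3 (-1.51 ± 0.15), EREG (-1.35 ± 0.25) and OSTM1 (-1.27 ± 0.22) fell most. Of 31 YAP/TAZ targets 13 rose and 0 fell (18 rose adjusted over the list alone), with THBS1 up by 1.92 ± 0.15, AMOTL2 by 1.44 ± 0.10, EDN1 by 1.41 ± 0.13, CTGF by 1.31 ± 0.13 and CYR61 by 1.26 ± 0.13. The camera adjusted p was 5.8e-14, with adjusted p = 0.133 with an estimated correlation. CDKN1A differed by 0.08 ± 0.19 (adjusted p = 0.868).

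Of 29 epithelial junction genes 8 rose and 1 fell (12 and 1 adjusted over the list alone), with CLDN1 up by 1.61 ± 0.09, a camera adjusted p of 1.9e-07 and adjusted p = 0.23 with an estimated correlation, and CDH1 rose by 0.87 ± 0.12. Of 12 luminal markers 5 rose (6 up and 1 down adjusted over the list alone; camera, adjusted p = 0.0029; adjusted p = 0.50 with an estimated correlation). None of 40 G2/M genes and 1 of 40 S phase genes, CCNE2 (0.55 ± 0.11), passed, and 0 of either list adjusted over the list alone. With the batch as a block 10 G2/M genes fell and 0 rose, and 6 S phase genes rose and 6 fell. The G2/M list had a median of -0.11 and a camera adjusted p of 0.0018 (adjusted p = 0.80 with an estimated correlation), a call lost without siLATS_p53 replicate 2 (0.155). Adhesion genes, with MYL9 up by 2.23 ± 0.18 among 6 of 41 that rose, and Hippo components, with VGLL3 up by 1.09 ± 0.12 among 2 of 28, passed camera (0.023 and 0.037; 11 up and 2 down, and 5 up and 1 down, adjusted over each list alone), and both had adjusted p = 0.50 with an estimated correlation. These calls were lost without sip53 replicate 1 (0.172 for both) and without siLATS_p53 replicate 2 (0.150 and 0.0631). Of 30 interferon-stimulated genes 0 passed singly and 20 rose with the block, with a camera adjusted p of 0.00015 and adjusted p = 0.80 with an estimated correlation. That call was lost without the 2 shallowest libraries (median 0.716). Lists not called here that passed camera with the block were basal markers (down, 0.0018), fibroblast markers (up, 0.045) and histone genes (up, 0.035). Their camera adjusted p-values with an estimated correlation and no block were 0.80, 0.50 and 0.50.

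In all, 451 genes passed for LATS1/2 knockdown on top of p53 knockdown, 313 higher (69.4%) and 138 lower, against 2720 with the block. The count was 188 without siLATS replicate 1, 189 without siLATS replicate 2, 82 without sip53 replicate 1, 72 without sip53 replicate 2, 66 without siLATS_p53 replicate 1 and 49 without siLATS_p53 replicate 2. Of the 51 called genes named by rule, 17 passed whichever library was left out.

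**Figure D3:**
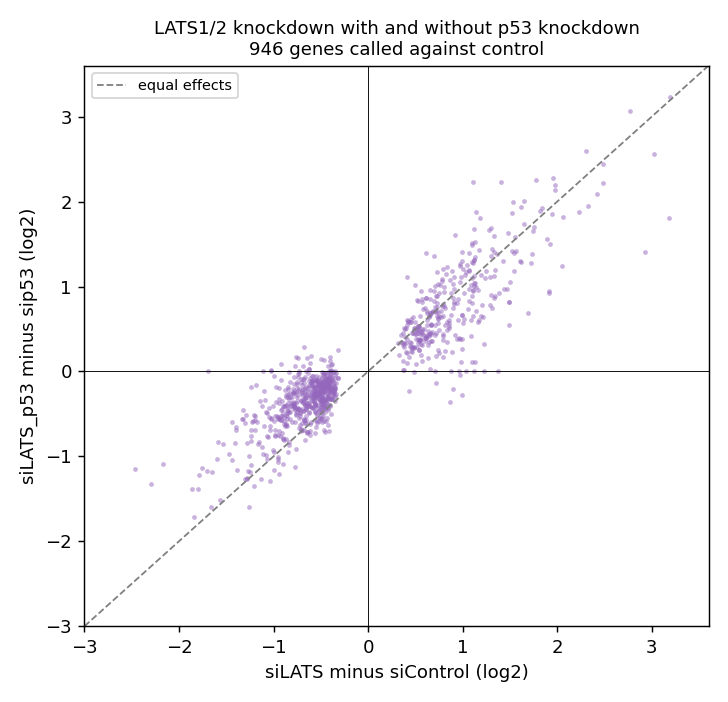
Log2 difference siLATS_p53 minus sip53 (vertical axis) against siLATS minus siControl (horizontal axis) for the 946 genes called for LATS1/2 knockdown against control, the targeted genes left out. Each point is a gene, the dashed line marks equal effects, and 904 of the genes have the same sign on both axes.

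The effects of LATS1/2 knockdown with and without p53 knockdown were set side by side, using contrasts that share no library. Over the 946 genes called against control, the slope across genes was 0.745 and 904 (95.6%) had the same sign. Over the 449 genes called in the other contrast, the slope was 0.955 and 442 had the same sign, so that the choice of genes moved the slope, and genes are not independent replicates. Over all 12312 genes tested outside the targets, the slope was 0.665 and 8350 (67.8%) had the same sign. The interaction test of each gene called 0 genes with limma, with 807 at an unadjusted p under 0.05, and 250 (216 higher and 34 lower) with the batch as a block. With the block and rescaling there were 65, 41 higher and 24 lower. Among genes above the median expression level, the largest interactions were those of ELF3 (1.32 ± 0.41), IL8 (1.32 ± 1.44), JPH2 (1.06 ± 0.19), ANGPTL4 (1.00 ± 0.23) and SERPINB1 (0.97 ± 0.17), and on the negative side XDH (-0.73 ± 0.38), CLCA2 (-0.67 ± 0.18), SERPINB13 (-0.66 ± 0.22), TOB1 (-0.63 ± 0.29) and DRAM1 (-0.63 ± 0.20). With the block all of these but TOB1 (adjusted p = 0.062) passed, with adjusted p-values from 0.0026 for ELF3 to 0.045 for IL8.

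Calls against control were compared between knockdowns, which share the siControl libraries. LATS1/2 and p53 knockdown had 57 calls in the same direction and 59 in opposite directions, beside 18.6 in the same direction for independent lists. No such value was computed for opposite directions, and the shared calls divided almost evenly, so they do not show a common direction. LATS1/2 and combined knockdown shared 454 in the same direction and 23 in opposite directions (64.1 for independent lists), and p53 and combined knockdown shared 359 and 10 (33.7). With unchanged groups simulated against the same controls, 0 such calls appeared in 100 draws. With no change in any group hardly any calls can arise, so this cannot show what shared controls add among genes that change. The correlations of fold changes across genes were 0.024, 0.58 and 0.63 beside simulated values of 0.50, and the covariances were 0.0029, 0.097 and 0.090 beside a simulated 0.0089. Unchanged groups of equal spread give a correlation near 0.50 whenever contrasts share a control, so that value is no benchmark for genes that change. Splitting the controls would leave 1 library in each part, so part of these overlaps may come from the shared controls.

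**Figure D4:**
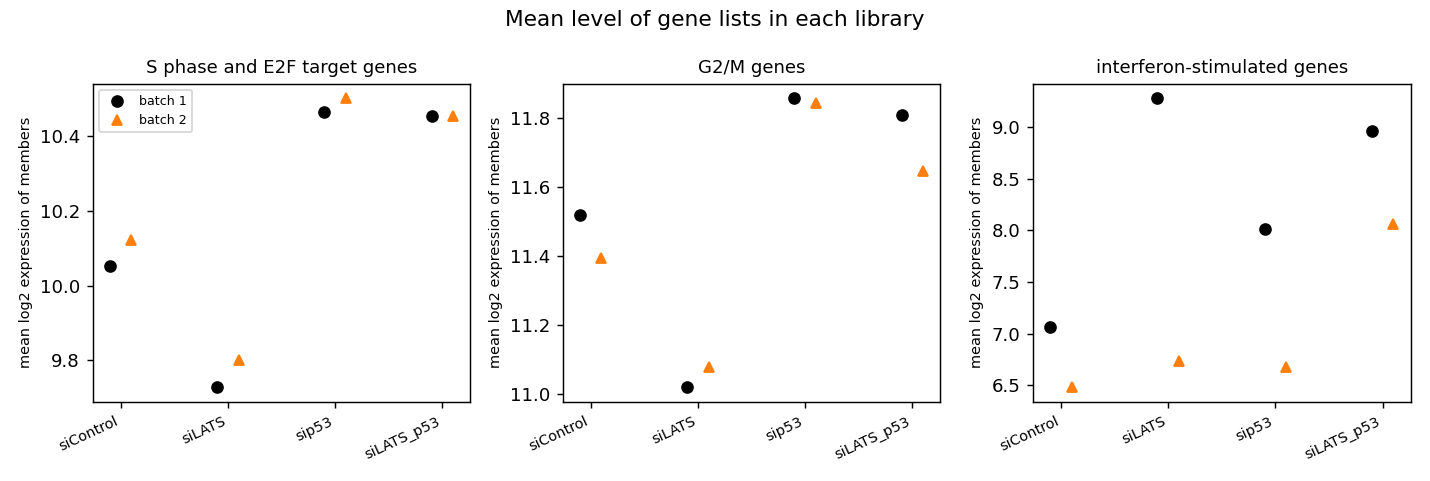
Mean log2 expression of the members of 3 gene lists (vertical axes, each with its own range) in the 8 libraries, by group (horizontal axes), with batch 1 as circles and batch 2 as triangles. Cell division lists were lowest in siLATS in both batches, and interferon-stimulated genes ranged from 6.48 in siControl 2 to 9.28 in siLATS 1.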

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

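The tests of explanations in this part and their limits were chosen after the results were seen, while rescaling and leaving out single libraries were alternatives fixed before. The results below are the gene lists whose response to LATS1/2 knockdown differed with p53 knockdown, by camera on the interaction without the batch block. The S phase list had a median interaction of 0.256 on the log2 scale (adjusted p = 2.8e-08), the G2/M list 0.304 (1.0e-08), adhesion and migration genes 0.198 (0.0048), NF-kB genes 0.464 (0.0080) and p53-activated targets -0.025 (0.013), beside 0.097 for all genes. With the block squamous markers (up, 0.019) and interferon-stimulated genes (down, 0.041) passed as well, and squamous markers also passed after rescaling (0.0105). The interferon call has no stable direction, with medians of -0.949 in batch 1 and 0.935 in batch 2, and turned upward without siLATS replicate 1 (0.98, 4.3e-06). None of the first 5 passed with an estimated correlation (lowest adjusted p = 0.36). In that test, without the block, squamous markers and interferon-stimulated genes each had adjusted p = 0.90. The adhesion call was lost without sip53 replicate 1 (0.0779) and siLATS_p53 replicate 2 (0.172), the NF-kB call without siControl replicate 1 (0.398), siLATS replicate 2 (0.151) and siLATS_p53 replicate 2 (0.123). The p53 target call was lost without siControl replicate 1 (0.378), siLATS replicate 2 (0.0972), sip53 replicate 1 (0.0719) and siLATS_p53 replicate 2 (0.123). Without the 2 shallowest libraries the G2/M call was lost (median 0.147), as were the NF-kB (0.1145) and p53 target (0.042) calls.

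S phase and G2/M genes fell more with LATS1/2 knockdown alone than where p53 was knocked down too. Scaling of whole libraries, which moves all genes alike, was not tested as a cause, because camera already compares a list with the other genes. Against the shallow batch 1 libraries as the cause, the S phase median in batch 2 alone exceeded that of all genes by 0.183. For the G2/M list that excess was 0.028. The G2/M median interaction was 0.304 with all libraries and 0.147 without the 2 shallowest. Both of these, siControl 1 and siLATS_p53 1, are in batch 1, so their removal cannot tell depth from another trait of them. It also leaves siControl and siLATS_p53 with batch 2 alone, in a fit without the block, so batch differences enter that value. All 40 G2/M members lay above the floor in both, with mean log2 levels of 11.519 and 11.808. That argues against depth acting through the floor, and no other effect of depth was tested. Growth differences between single dishes stay open, because the interaction of both lists was 2.82 times its standard error over libraries, below the 6.85 needed over 21 lists. A biological explanation, p53 activity raised by LATS1/2 knockdown, also stays open, since p53-activated targets lay only 0.076 above other genes.

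Interferon-stimulated genes were higher in LATS1/2 knockdown libraries, unevenly between the batches. A batch difference alone is argued against for siLATS_p53, whose list median was at least 1.53 above siControl within each batch. For siLATS the median was 1.83 above siControl in batch 1 and 0.023 in batch 2, so its rise rests on siLATS replicate 1. A difference shared by a batch cancels within it, but these values cannot tell a treatment effect from a trait of that library. A response to siRNA that grows with the number of genes targeted may contribute, but siLATS_p53 minus siLATS was -0.20 in batch 1 (bootstrap standard error 0.135) and 1.27 in batch 2, which decides neither way. The same smallest value of 0.023 leaves LATS1/2 knockdown itself open, and sip53, without LATS siRNA, was also uneven, 0.829 above siControl in batch 1 and 0.023 in batch 2. In siControl 2 only 15 of 30 members lay above the floor, which understates differences in batch 2.

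Most genes called for p53 knockdown on top of LATS1/2 knockdown were higher. Rescaling by medians of ratios brought the share of higher calls from 77.9% to 45.8%, but it removes a median shift whatever its cause, so it cannot tell scaling from biology. A larger share of signal in the 100 highest entries of siLATS would shift the other genes by 0.075, beside median shifts of 0.173 and 0.127 in the batches, and could account for part of them. No biological explanation was tested.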

How the results depend on the processing

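Added after seeing the data were the block with rescaling, leaving out the 2 shallowest libraries, rescaling for slopes and overlaps, and, as an alternative, the pseudocount of 1 that the design had named. In the order LATS1/2, p53, combined, p53 on LATS1/2, LATS1/2 on p53 and interaction, calls were 948, 475, 1792, 1791, 451 and 0. With the replicate block, which models the pairing by batch, they were 3937, 3199, 4832, 5361, 2720 and 250. With the block and rescaling they were 3412, 2975, 4659, 4153, 2737 and 65. With only the groups compared, the first 5 were 0, 0, 374, 0 and 0, with 2 residual degrees of freedom. Without the 2 shallowest libraries all 6 were 0 with limma. Leaving out 1 library gave 43 to 700, 18 to 165, 553 to 1265, 12 to 1837, 49 to 362 and 0 to 0, and 37 to 47 list calls instead of 40. Fewer samples enter these fits, and none of them had the batch block. Where the library left out belongs to a group outside the comparison, the fold changes stay the same and only the estimate of spread changes. Where it belongs to a compared group, the batches become unbalanced and their differences enter the fold changes. How much this moved the counts was not tested. Rescaling, filters and pseudocounts kept each of the 6 counts within 1.5 times.

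Of 126 list tests, 2 passed with an estimated correlation and 22 with fry, against 40. The block ended none of the 40 and added 14. Without siLATS replicate 1, camera turned upward for interferon-stimulated genes in p53 on LATS1/2 (median 1.60) and in the interaction (0.98). Without siLATS replicate 2 both moved downward, the direction camera gave with all libraries (-0.589 and -1.09). These fits set a lone siLATS library against groups from both batches, so batch differences enter them. Within batch 2 the medians were 1.27 and 0.935, and within batch 1 they were -0.20 and -0.949. The slope of LATS1/2 effects was 0.955 for genes chosen in the other contrast. LATS1/2 and p53 knockdown shared 590 calls in the same direction and 769 in opposite directions with the block, and 4 and 11 at an adjusted p under 0.01, against 57 and 59. Of the called named genes none reversed in any setting. DESeq2 and voom fits were not run, because they need counts. The fixed floor limits low genes, since it stood for 14.6 to 50 estimated reads, the most in the deepest library, siLATS 1.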

Other observations

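The tests of batch differences in this part were chosen after the data were seen, and no explanation of them was tested. The 2 batches of untransformed MCF10A cells differed from each other in all 4 groups. With group and batch in the limma fit, 3732 of 12315 genes differed between batches, 1541 higher and 2191 lower in batch 2, and 163 at least 2-fold. Genes of stratified keratinocytes were higher in batch 2, such as A2ML1 (1.40), the cornified envelope gene SPRR1B (1.05) and the basal keratin gene KRT14 (0.79), on the log2 scale. The class I histocompatibility gene HLA-B (-2.19), NUP210 (-1.92), IL8 (-1.88), SPARC (-1.85) and LCP1 (-1.80) were lower. Interferon-stimulated genes were lower in 26 of 30 cases (median -1.06, camera adjusted p = 8.2e-12). Squamous markers were higher in 14 of 22 and lower in 1 (2.1e-09), and basal markers higher in 12 of 19 and lower in 2 (5.9e-07). By camera, luminal markers (0.0026), NF-kB (0.0091) and mesenchymal genes (0.033) also moved down. Immediate early (0.00093), adhesion and migration (0.027) and S phase genes (0.033) moved up. None of these lists passed with an estimated correlation, with adjusted p = 0.28 or above. The genes named here were chosen after their values were seen. The lower ones were taken by size among called genes above the median expression level. The keratinocyte genes were not taken by size alone, since INHBA (0.97) was passed over.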
